A study of Homo sapiens with 14 samples.

How the data were processed

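The material was total RNA from human mixed glial cultures (mainly microglia, per the labels) and from monocyte-derived macrophages (MDM), each without and with serum, hybridised singly to 14 one-colour oligonucleotide arrays. Samples were grouped by cell type and serum from their titles. For replicate numbers 16 and 18 of mixed glia the title alone gives the serum state, since their descriptions leave out the activation status. Replicate numbers are those of the titles.

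The deposited table held 1 intensity per probe set and array, for 12625 probe sets, on a linear scale with no value below 0 and 3 values equal to 0. The software and the scaling that the authors used to make these intensities are not given in the sources used here. The means of the columns after 2% was trimmed at each end ran from 31.34 to 187.5, a ratio of 5.98, so the columns did not agree within the 5% that scaling to a common target would give and were treated as not normalized. No background measure or detection call was used here, so low values were handled by the filter alone.

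A pseudocount of 7.3 intensity units, the 25th percentile of all values, was added before log2 was taken, so that the differences of dim probe sets are understated. The log2 values were quantile normalized with limma 3.58.1 in R 4.3.3. The 67 control probe sets were removed, leaving 12558. A probe set was kept when the third highest of its 14 values exceeded the median log2 value of the table, 5.21, and 7374 were kept. Gene names came from the platform annotation, updated through Entrez numbers to the RefSeq table of assembly GRCh38.p14, which matched 10949 of the 10961 probe sets with 1 symbol and changed 0 symbols. Of the 12558 probe sets, 10943 had 1 gene symbol, 545 had several and 1070 were not listed. Those with several or none stayed in the tests and are not named. The kept probe sets covered 5374 genes. No genome build is stated for the array, so no coordinates are given. Probe sets with _s or _f in their names can hybridise with transcripts of related genes.

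All groups entered 1 limma fit (lmFit and eBayes) of 4 group means, with the contrasts serum in mixed glia, serum in MDM, the difference of these serum effects, and mixed glia against MDM without and with serum. The comparison of cell types averaged over serum used the mean of both arrays of each number, 4 numbers against 3, in a fit of its own. All tests were two-sided with Benjamini-Hochberg adjustment over the 7374 probe sets and a threshold of 0.05. Errors of differences are standard errors of the fit, and group means carry their SD. The replicate block added the replicate number as a term. Errors and p-values of serum effects are those without it unless stated, and these keep the spread between numbers.

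Whether the replicate numbers pair the samples was checked before the fits were compared. In all 7 pairs the arrays of a number deviated together from their group means, with correlations from 0.464 to 0.727, while the highest between different numbers across serum states was 0.122. The numbers were therefore taken to pair the samples. This comes from the data, since no label states a shared donor. Transcripts linked to sex disagreed in 0 of 7 pairs.

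Sets of genes were fixed before the data were examined: 24 lists, 9 of cell types and 15 of pathways. The cell type lists were microglia-enriched, monocyte and macrophage, pan-myeloid, astrocyte, oligodendrocyte lineage, neuron, fibroblast and mural, endothelial, and lymphocyte genes. The pathway lists were inflammatory cytokines and NF-kB targets, interferon response, MHC class II presentation, immediate early serum response, cell cycle, cholesterol and fatty acid synthesis, lipid uptake, storage and efflux, phagocytic and scavenger receptors, hypoxia and glycolysis, heat shock, amino acid and unfolded protein stress, lysosome, matrix proteases and inhibitors, oxidative stress and metal response, and complement. Some members were not on the table or were removed by the filter, and measured members are those the filter kept. Of the 20 microglia-enriched genes 10 were on the table and 7 were kept, with P2RY12, TMEM119 and TREM2 not used here. Of the 16 astrocyte genes 15 were on the table and 10 were kept. Lists were tested with camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean, adjusted over the 24 lists of a comparison. With an estimated correlation in place of the preset one, 4 of the 10 calls for serum in mixed glia held, and none of the 6 for serum in MDM, the 5 for the difference or the 6 for the cell types. Camera compares a list with the other genes, while fry tests whether the genes of a list move, on balance, one way. Counts of members past the threshold are given over all probe sets and adjusted over the list alone. The test and the median of a list differed in sign for 1 list in mixed glia, 3 in MDM, 4 for the difference and 4 for the cell types.

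Genes were named by a rule fixed at the same time. It took the 10 largest changes per direction among probe sets past the threshold that moved the same way in every pair, or whose number means did not overlap between cell types. A direction with fewer than 5 was filled to 5 by the smallest unadjusted p, under the same condition on pairs or number means. For the difference of serum effects the direction was filled to 3 with no condition on pairs. Up to 4 members per list were added, those past the threshold first and then the largest. Genes named outside this rule are said to be so where they appear.

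The fits were tested on simulated data with the means and spreads of the 7374 probe sets, in which 100 probe sets were changed by 1 and 100 by 2 on the log2 scale. For serum in mixed glia 32% and 91% of these were recovered, and 62% and 98% with the replicate block. For serum in MDM the shares were 13% and 70%, and 46% and 86% with the block. For the difference of serum effects they were 3% and 41%, and 22% and 66% with the block. The comparison of cell types over number means recovered 26% and 84%, that without serum 39% and 81% and that with serum 29% and 81%. Unchanged probe sets were 15 of 135 calls for the cell types without serum and 8 of 118 with serum. Over number means they were 3 of 113. For serum they were 2 of 125 in mixed glia and 1 of 84 in MDM, and for the difference 0 of 44. With the block the last groups had 7 of 167, 7 of 139 and 3 of 91, in that order. Camera recovered 20 of 20 lists shifted by 0.5 in each comparison, and called 1 of 20 unshifted lists for the difference and 0 of 20 in the others. The simulated probe sets were drawn independently of each other. This therefore does not test the preset correlation on lists whose genes move together.

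Alternatives were the pseudocount at the 10th (2.4) and 50th (27.9) percentile, no filter and a stricter one at the 70th percentile, the deposited scale, centring on the median, limma-trend, array weights, 1 probe set per gene, a minimum change of 2-fold, the replicate block, fits on 1 cell type or serum state, random or no blocks for the cell types, and each replicate number left out in turn. In fits with arrays left out, the normalization and filter of all 14 arrays were kept. For the lists, camera with an estimated correlation, fry, the deposited scale, no filter and the mean over all probe sets of a gene were run.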

Results

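Gene expression was profiled on 14 oligonucleotide arrays in 2 kinds of human cell preparation. One was a primary culture of mixed glial cells that the labels describe as mainly microglia, the resident macrophages of the brain. The other consisted of monocyte-derived macrophages (MDM), which are blood monocytes that have matured into macrophages. Each preparation was measured without and with serum, and the labels equate serum with activation. The groups held 4 arrays of mixed glia without serum, 4 of mixed glia with serum, 3 of MDM without serum and 3 of MDM with serum. Mixed glia carried the replicate numbers 1, 7, 16 and 18 and MDM the numbers 8, 14 and 17, with each number present once without and once with serum. No label gives the serum dose or the time in culture. No label says which samples share a donor, so the p-values measure the spread between these samples.

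The arrays differed in brightness. Their median intensity ran from 11 to 69 units, and the 4 arrays of replicate numbers 1 and 8 were the dimmest, between 11 and 15.4. The ratio of the 3 prime to the 5 prime control probe set of ACTB, a measure of RNA integrity, was 13.7 on the array of mixed glia without serum, replicate 7, against 1.03 to 2.56 on the other 13 arrays. For GAPDH the corresponding values were 3.35 and 0.903 to 1.83. Across the 7374 probe sets kept, the arrays of the same number had a median Spearman correlation of 0.909. That median was 0.849 between different numbers of a cell type and 0.804 between the cell types. The number of arrays limits the precision of every value given here.

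The first comparison asked which genes changed with serum in mixed glia. Transcripts of secreted inflammatory and tissue-remodelling proteins were among those that rose most. S100A8, a calcium-binding protein of activated myeloid cells, rose by 3.90 ± 0.68 (SE, n = 4 per group) on the log2 scale, with an adjusted p of 0.02. CCL2, the main monocyte chemoattractant, rose by 3.68 ± 0.51 (adjusted p = 0.005), with its other 2 probe sets at 3.27 and 0.84, and IL1B, an inflammatory cytokine, rose by 3.58 ± 0.71 (adjusted p = 0.045). MMP12, the macrophage elastase, rose by 3.44 ± 0.69 (adjusted p = 0.047) and TIMP1, an inhibitor of metalloproteinases, by 2.95 ± 0.43 (adjusted p = 0.005). MRC1, the macrophage mannose receptor, went from a log2 level of 5.0 ± 0.68 (SD, n = 4) without serum to 8.40 ± 0.51 with serum, a rise of 3.41 ± 0.40 with an adjusted p of 0.0017. The others among the 10 largest rises that passed were the growth factor HBEGF (2.80), the matrix protein TGFBI (2.69) and the transcriptional regulators ID3 (2.58) and CREM (2.43). CREM was at 2.74 on the deposited scale and did not pass (adjusted p = 0.21).

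Without the replicate block 4 probe sets fell with serum in mixed glia, against 100 with the block and 0 on the deposited scale, where the 4 genes named here lost their call. ITGA3, an integrin subunit, fell by 2.20 ± 0.43 (adjusted p = 0.044), and SLC6A12, a transporter of betaine and GABA, fell by 2.04 ± 0.28 (adjusted p = 0.005). LGALS3, the lectin galectin-3, fell by 1.48 ± 0.26 (adjusted p = 0.021), and PDE8A, a cyclic AMP phosphodiesterase, fell by 1.05 ± 0.21 (adjusted p = 0.044). CDC42EP3, an effector of a small GTPase, was next with a difference of -1.20 ± 0.25 that did not pass (adjusted p = 0.063, and 0.013 with the replicate block).

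**Figure D1:**
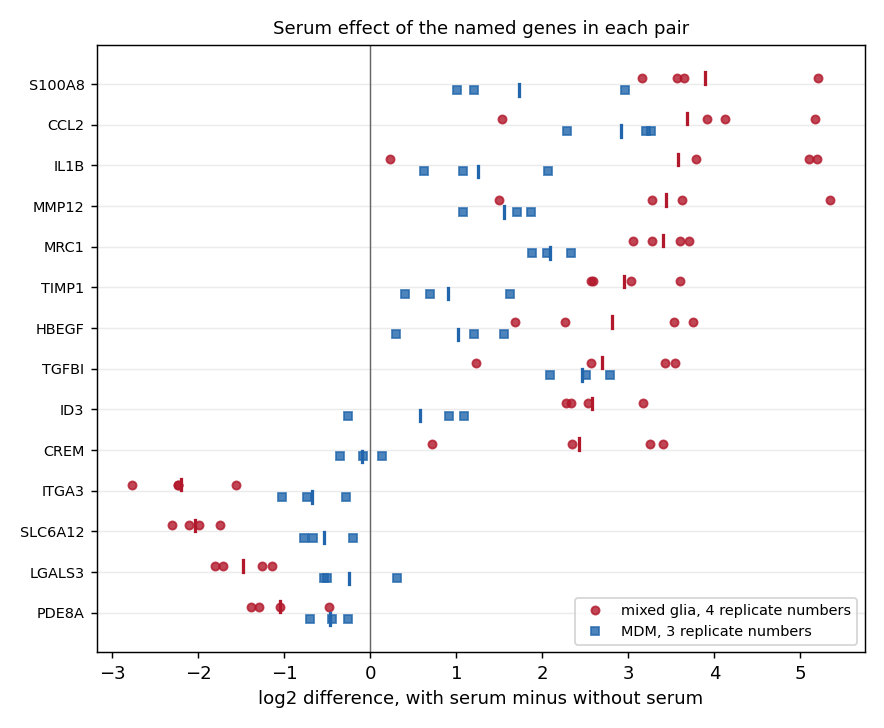
Each point is the log2 difference between the array with serum and the array without serum of the same replicate number (x axis) for the 14 named genes that passed the test in mixed glia (y axis), with red circles for the 4 mixed glia pairs, blue squares for the 3 MDM pairs and vertical bars for their means. For MRC1 the mixed glia pairs lie between 3.05 and 3.70 and the MDM pairs between 1.88 and 2.33.

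In all, 27 of 7374 probe sets passed an adjusted p of 0.05 in limma for serum in mixed glia, 23 higher and 4 lower, and all 27 moved the same way in 4 of 4 pairs. Chance gives that for 12.5% of unselected probe sets, which is no measure for these 27, selected on the same arrays. With the replicate number as a block, 201 passed, 101 higher and 100 lower, among them all 27. The count without the block fell to 5 when replicate 1 was left out and to 7 when replicate 18 was left out, and no probe set passed without the pairs of numbers 1 and 8, where the block gave 48. Of the 14 named genes that passed, only MRC1 kept its call without the block whichever replicate number was left out. With the block and all numbers, all 14 kept it. For single genes no number was left out with the block, so their dependence on 1 number under the pairing is not known.

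Receptors for uptake of particles and ligands rose as a group with serum in mixed glia. The 15 measured phagocytic and scavenger receptors had a median difference of 1.07, 12 of them positive (camera adjusted p = 7.2e-09, and 0.039 with an estimated correlation). MRC1 passed over all probe sets, and 8 members passed when adjusted over the list alone. FCGR2A, an activating IgG receptor, differed by 2.42 ± 0.52 on the probe set tested for the list, CD14, the lipopolysaccharide co-receptor, by 1.67 ± 0.45 and STAB1, a scavenger receptor, by 1.64 ± 0.48. Over all probe sets these 3 passed with the replicate block and not without it (adjusted p = 0.0031, 0.022 and 0.0021). The list median was 0.0254 in the pair of replicate 1 and between 0.528 and 1.41 in the others.

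Inflammatory cytokines and NF-kB targets rose as well, with 16 of 18 members positive, a median of 0.50 and a mean of 1.09 (camera adjusted p = 1.1e-08, and 0.039 with an estimated correlation). IL1B, CCL2 and IL6 passed over all probe sets and 5 members passed when adjusted over the list alone. IL6, a cytokine of the acute phase, rose by 2.0 ± 0.36 (adjusted p = 0.024), a call lost on the deposited scale (adjusted p = 0.24). CXCL8, a neutrophil chemoattractant, differed by 2.70 ± 1.15 and passed with the block alone (adjusted p = 0.65 without it and 0.011 with it). TNF, chosen for mention after its value was seen, differed by 0.20 ± 0.21 on the probe set tested for the list. The list median was 0.80 without replicate 7 and 1.08 on the deposited scale.

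Matrix proteases and their inhibitors rose with a median of 0.81 (camera adjusted p = 7.9e-06, and 0.041 with an estimated correlation). Of the 11 measured, 9 were positive, 1 passed and 3 passed when adjusted over the list alone. Besides TIMP1, TIMP3 differed by 1.13 ± 0.49 and PLAU, the urokinase plasminogen activator, by 1.05 ± 0.30, neither past the threshold over all probe sets. Genes of hypoxia and glycolysis rose with a median of 0.51 and 16 of 18 members positive (camera adjusted p = 6.4e-07, and 0.019 with an estimated correlation). None of them passed singly over all probe sets and 1 passed when adjusted over the list alone. LDHA, lactate dehydrogenase A, differed by 1.51 ± 0.39 and passed with the block (adjusted p = 0.0059), as did BNIP3 at 0.86 ± 0.35 (adjusted p = 0.047) and the glycolytic enzyme TPI1 at 0.79 ± 0.25 (adjusted p = 0.049). The matrix median was 1.25 without replicate 7, and that of hypoxia and glycolysis 0.84 on the deposited scale.

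The 3 lists of myeloid cells also passed camera in the upward direction with serum in mixed glia, that of monocytes and macrophages with as many members lower as higher. All 7 measured microglia-enriched genes were positive, with a median of 0.37 (camera adjusted p = 1e-04, and 0.11 with an estimated correlation). None passed over all probe sets and 2 passed when adjusted over the list alone. CSF1R, the receptor for the growth factors of macrophages, differed by 1.87 ± 0.42 and MERTK, a receptor for apoptotic cells, by 1.07 ± 0.30, and both passed with the block (adjusted p = 0.0063 and 0.04). The monocyte and macrophage list had a median of 0.08 and a mean of 0.66, with 8 of 16 members positive (camera adjusted p = 0.0052, 0.11 with an estimated correlation and 0.087 with the replicate block). S100A8 and MRC1 passed, and adjusted over the list alone 5 passed higher and 1 lower. S100A9, the partner of S100A8, differed by 2.69 ± 0.74 and passed with the block (adjusted p = 0.0023). Pan-myeloid genes had a median of 0.40 with 13 of 16 positive, none passing and 1 passing when adjusted over the list alone (camera adjusted p = 0.018, and 0.45 with an estimated correlation). That call was lost without replicate 16 (median 0.26, adjusted p = 0.094). The microglia-enriched median was 0.63 without replicate 16, and that of monocytes and macrophages 0.14 without replicate 7, -0.02 without replicate 18 and 0.03 with no filter. These 3 lists had medians of 0.72, 0.13 and 0.77 on the deposited scale, in the order given. Beside these lists, oligodendrocyte lineage genes had a median of -0.37 that did not pass (camera adjusted p = 0.25), with pair medians from -1.17 to 0.05.

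Interferon response genes fell as a group with serum in mixed glia. The 22 measured had a median of -0.62 with 19 negative, but none passed singly, over all probe sets or when adjusted over the list alone (camera adjusted p = 7.9e-06, and 0.29 with an estimated correlation). IFI27 differed by -1.61 ± 0.56, the antiviral GTPase MX1 by -1.49 ± 0.44 and the RNA-binding IFIT1 by -1.31 ± 0.46, and the last pair of genes passed with the block (adjusted p = 0.014 and 0.027). The list median was negative in all 4 pairs, from -1.10 to -0.13. Without replicate 7, whose array without serum had the high 3 prime to 5 prime ratio, it was -0.62. On the deposited scale, where the median of all probe sets was 0.332, it was -0.27 and the list passed (adjusted p = 3.3e-09).

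Genes of lipid uptake, storage and efflux fell with a median of -0.41 and 11 of 15 members negative (camera adjusted p = 0.0034, and 0.29 with an estimated correlation). None passed over all probe sets and 3 passed lower when adjusted over the list alone. NR1H3, the oxysterol receptor LXR alpha, differed by -1.63 ± 0.55, the cholesterol exporter ABCG1 by -1.36 ± 0.60 and the lipid droplet protein PLIN2 by -1.25 ± 0.51. NR1H3 and PLIN2 passed with the block (adjusted p = 0.02 and 0.009). Replicate 7, with the high 3 prime to 5 prime ratio, had the largest shift (-0.98), and without it the list median was -0.12 and the adjusted p 0.079, while without replicate 1 the median was -0.84. Lysosomal genes had a median of -0.33 with 16 of 20 negative and none passing, over all probe sets or when adjusted over the list alone (camera adjusted p = 0.034, and 0.49 with an estimated correlation). The protease CTSK differed by -1.05 ± 1.04 and the ganglioside-binding GM2A by -0.90 ± 0.39, both past the threshold with the block (adjusted p = 0.037 and 0.013). The lysosomal call was lost without replicate 1 (adjusted p = 0.12) and without replicate 16 (adjusted p = 0.064), and without the pairs of numbers 1 and 8 (adjusted p = 0.16). The lipid median was -0.10 and the lysosomal one -0.02 on the deposited scale. The other 3 probe sets of GM2A lay between -0.28 and 0.02.

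**Figure D2:**
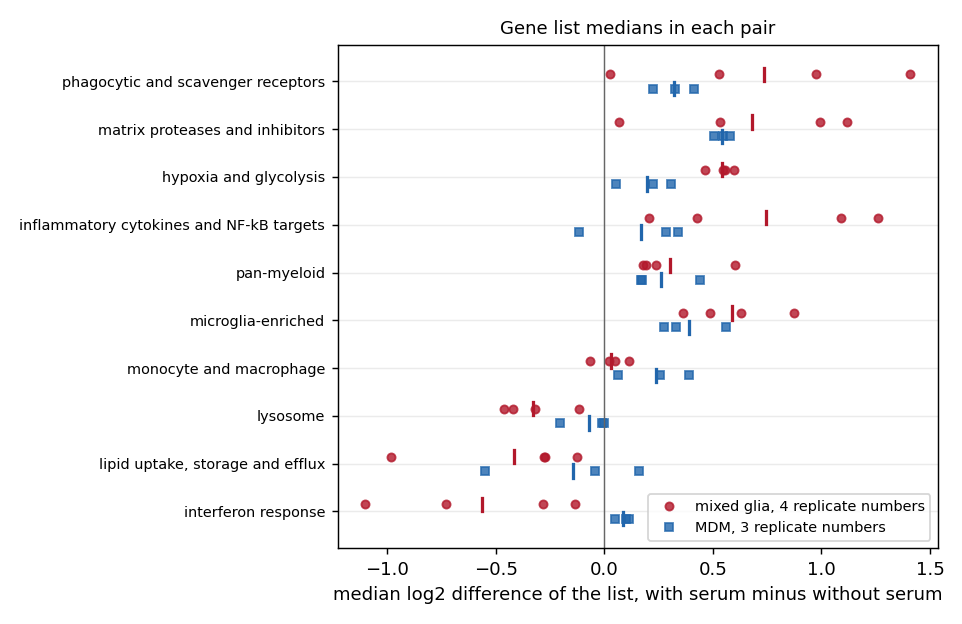
Each point is the median log2 difference, with serum minus without serum (x axis), of the measured members of a gene list (y axis) in 1 pair of arrays with the same replicate number, for the 10 lists that passed camera in mixed glia, with red circles for the 4 mixed glia pairs, blue squares for the 3 MDM pairs and vertical bars for their means. The interferon response medians are negative in all 4 mixed glia pairs, from -1.10 to -0.13, and lie between 0.05 and 0.11 in the 3 MDM pairs.

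The second comparison asked the same question in MDM. No probe set passed the threshold there in limma (0 of 7374). An unadjusted p under 0.05 was found for 130, or 1.76%, where chance gives 5% with no change. This fit leaves out the pairing by number and keeps the spread between numbers in its error. Its low share is therefore no evidence against a serum effect. The 5 higher probe sets named by the smallest p were TGFBI with 2.46 ± 0.45 (SE, n = 3 per group, adjusted p = 0.45), CCL2 with 2.92 ± 0.59 (adjusted p = 0.65), MRC1 with 2.09 ± 0.46 (adjusted p = 0.77), the fatty acid receptor PPARD with 0.99 ± 0.26 and the zinc transporter SLC39A8 with 1.61 ± 0.44. On the lower side they were KCNE1 (-1.05), MT3 (-1.04), CLIP2 (-0.78), SHROOM2 (-1.55) and RARG (-0.97), each with an adjusted p of 1. The other 2 probe sets of CCL2 were at 2.81 and 0.04, the other of MT3 at -0.10 and the other 2 of RARG at 0.06 and 0.58. The rule for naming took only probe sets with the same sign in 3 of 3 pairs, so that agreement is no result. With the replicate block 1 probe set passed, that of MRC1 (adjusted p = 0.0068), and 585 (7.93%) had an unadjusted p under 0.05.

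As groups, 6 lists were shifted upward with serum in MDM in camera and none downward, and none of the 6 held with an estimated correlation. Phagocytic and scavenger receptors had a median of 0.36 with 14 of 15 positive (adjusted p = 0.00079, and 0.29 with an estimated correlation). FCGR3A, an IgG receptor, differed by 1.73 ± 0.60 and MERTK by 0.74 ± 0.35. Microglia-enriched genes had a median of 0.35 with 7 of 7 positive (adjusted p = 0.003, and 0.29 with an estimated correlation), C1QB with 1.46 ± 0.71. Monocyte and macrophage genes had a median of 0.17 with 12 of 16 positive (adjusted p = 0.0068, and 0.29 with an estimated correlation), S100A8 with 1.73 ± 0.78. Matrix proteases and inhibitors had a median of 0.50 with 9 of 11 positive (adjusted p = 0.007, and 0.29 with an estimated correlation), MMP7 with 1.79 ± 0.83. Pan-myeloid genes had a median of 0.39 with 12 of 16 positive (adjusted p = 0.016, and 0.70 with an estimated correlation). Genes of cholesterol and fatty acid synthesis had a median of 0.37 with 14 of 19 positive (adjusted p = 0.007, and 0.70 with an estimated correlation), MSMO1 with 1.26 ± 0.90 and FADS2 with 1.18 ± 0.80. No member of these lists passed over all probe sets. Adjusted over the list alone, 1 member passed in the receptor list and 1 in the monocyte and macrophage list, MRC1 in both. The calls of the pan-myeloid and matrix lists were lost without replicate 14 (adjusted p = 0.063 and 0.062), the first with a median of 0.12, and that of the synthesis list without replicate 17 (median 0.24, adjusted p = 0.21). The matrix call was also lost with no filter (median 0.24, adjusted p = 0.14), and the monocyte and macrophage median was 0.31 without replicate 8. On the deposited scale, where the median of all probe sets was 0.234, the medians of the receptor, monocyte and macrophage, matrix, pan-myeloid and synthesis lists were 0.60, 0.44, 0.80, 0.68 and 0.69.

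Probe sets that passed with serum in mixed glia were then looked up in MDM, which share no array with mixed glia. Of the 23 higher ones, 18 were also higher in MDM, with a median of 0.66 there against 2.25 in mixed glia (camera p = 4.1e-14, and 0.0053 with an estimated correlation). These 23 probe sets covered 18 genes with a symbol, and several probe sets of a gene count separately here. All 4 lower ones were lower in MDM, with a median of -0.51 against -1.76 (camera p = 0.001, and 0.015 with an estimated correlation). Selection on the mixed glia arrays enlarges the mixed glia medians and not those of MDM. The gap between them is therefore no measure of a weaker response in MDM. CREM, which rose by 2.43 in mixed glia, differed by -0.10 in MDM. Among those found with the replicate block, 87 of 101 higher and 78 of 100 lower probe sets had the same sign in MDM. Across all 7374 probe sets, which are not independent replicates, the serum differences of the cell types had a Pearson r of 0.341 and a Spearman rho of 0.26.

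The third comparison tested the serum effect of mixed glia minus that of MDM. No probe set passed in limma, without or with the replicate block (smallest adjusted p = 0.2 with it). An unadjusted p under 0.05 was found for 140 without the block and 580 with it, or 1.9% and 7.87% against 5% by chance. The low share without the block comes with the spread between numbers left in the error and is no evidence against a difference. With the block and without the number 7 pair 9 passed, 8 higher and 1 lower. The 3 highest by p were THBD, the anticoagulant receptor thrombomodulin (2.02 ± 0.42), IL6 (2.54 ± 0.55) and ZFP36, which promotes the decay of cytokine mRNAs (1.65 ± 0.38). All 3 had risen with serum in mixed glia, by 1.92, 2.0 and 1.71, and differed by -0.10, -0.54 and 0.06 in MDM. The 3 lowest were MX1 (-2.61 ± 0.68), SLC6A12 (-1.49 ± 0.43) and the glutamate transporter SLC1A3 (-1.18 ± 0.35). MX1 was lower with serum in 4 of 4 mixed glia pairs and higher in 3 of 3 MDM pairs.

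For gene lists, 5 differed between the cell types in camera and none of them with an estimated correlation. Interferon response genes had a median difference of -0.76 with 18 of 22 negative (adjusted p = 2.4e-07, and 0.42 with an estimated correlation), among them IFIT3 at -1.63 ± 0.78. Inflammatory cytokines and NF-kB targets had a median of 0.41 with 14 of 18 positive (adjusted p = 0.00026, and 0.31 with an estimated correlation), CXCL8 at 3.43 ± 1.76. Phagocytic and scavenger receptors had a median of 0.33 with 10 of 15 positive (adjusted p = 0.012, and 0.63 with an estimated correlation), FCGR2A at 1.97 ± 0.79. Hypoxia and glycolysis genes had a median of 0.23 with 13 of 18 positive (adjusted p = 0.012, and 0.31 with an estimated correlation), VEGFA at 1.42 ± 0.70. Genes of cholesterol and fatty acid synthesis had a median of -0.44 with 15 of 19 negative (adjusted p = 0.015, and 0.75 with an estimated correlation), FADS2 at -1.51 ± 1.05. No member passed over all probe sets. Adjusted over the list alone, MX1 passed in the interferon list, IL6 in the inflammatory list and none in the other 3. Lysosomal genes (median -0.21, 19 of 20 negative) passed with the replicate block alone (camera adjusted p = 0.085 without it and 0.015 with it, and 0.82 without it with an estimated correlation). The synthesis call was lost without mixed glia replicate 7 (adjusted p = 0.16) or 18 (adjusted p = 0.086) and without MDM replicate 17 (median -0.28, adjusted p = 0.22). The receptor call was lost without mixed glia replicate 18 (median 0.21, adjusted p = 0.086) and the hypoxia call without MDM replicate 14 (adjusted p = 0.055). The receptor median was 0.51 without mixed glia replicate 16, and the inflammatory one 0.72 without mixed glia replicate 7.

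The fourth comparison set mixed glia against MDM, with the mean of both arrays standing for each replicate number (4 numbers against 3). IFI27, an interferon-induced gene, was higher in mixed glia by 4.21 ± 0.43 (SE, adjusted p = 0.0019), at a log2 level of 7.98 ± 0.91 (SD, n = 4) against 3.77 ± 0.10 (SD, n = 3). AXL, a receptor tyrosine kinase for apoptotic cells, was higher by 3.73 ± 0.34 (adjusted p = 0.00098) and OLR1, a receptor for oxidised lipoprotein, by 3.61 ± 0.47 (adjusted p = 0.0052). The other 2 probe sets of AXL were at 3.53 and 0.60, and its level of 3.07 in MDM lay near the lowest value of the normalized table, 2.88. C1QB, a chain of the complement protein C1q, was higher by 2.96 ± 0.49 (adjusted p = 0.016). The rest of the 10 largest were the protease HTRA1 (3.29), the membrane glycoprotein PDPN (3.16), the oxysterol enzyme CH25H (3.02), FCGR2A (2.86), the chemokine CCL8 (2.76) and the creatine synthesis enzyme GATM (2.57). The FCGR2A value is from an _f probe set, and its other probe set was at 1.67.

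Genes higher in MDM included FN1, the matrix protein fibronectin, with a difference of -3.95 ± 0.72 (adjusted p = 0.023), and GPC4, a cell surface proteoglycan, with -3.78 ± 0.48 (adjusted p = 0.0049). The FN1 value is from an _s probe set. Its other 2 probe sets were at -3.55 and -3.27, the first not past the threshold (adjusted p = 0.066). CD52, a surface glycopeptide of leukocytes, differed by -3.74 ± 0.54 (adjusted p = 0.0085) and FBP1, an enzyme of gluconeogenesis, by -3.52 ± 0.35 (adjusted p = 0.0015). The others were CIRSR (-3.64), the neuropeptide gene GAL (-3.57), the retinoic acid enzyme ALDH1A1 (-3.40), the cytidine deaminase CDA (-3.05), the cytoskeletal adaptor PSTPIP1 (-2.77, at a dim level of 3.60 in mixed glia) and the prostaglandin D synthase PTGDS (-2.59). In all, 155 probe sets passed in limma, 87 higher and 68 lower in mixed glia. All 155 had number means that did not overlap between the cell types. Chance gives that for 5.71% of unselected probe sets, which is no measure for these 155, selected on the same means. The count was 56 without MDM replicate 17, 83 without MDM replicate 8 and 56 without the pairs of numbers 1 and 8. On the deposited scale without normalization 49 passed, 19 higher and 30 lower, and with each array centred on its median 57 were higher and 64 lower. Of the 20 named genes, 15 kept their call whichever number was left out, and CH25H, FCGR2A, GATM, FN1 and PTGDS did not.

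**Figure D3:**
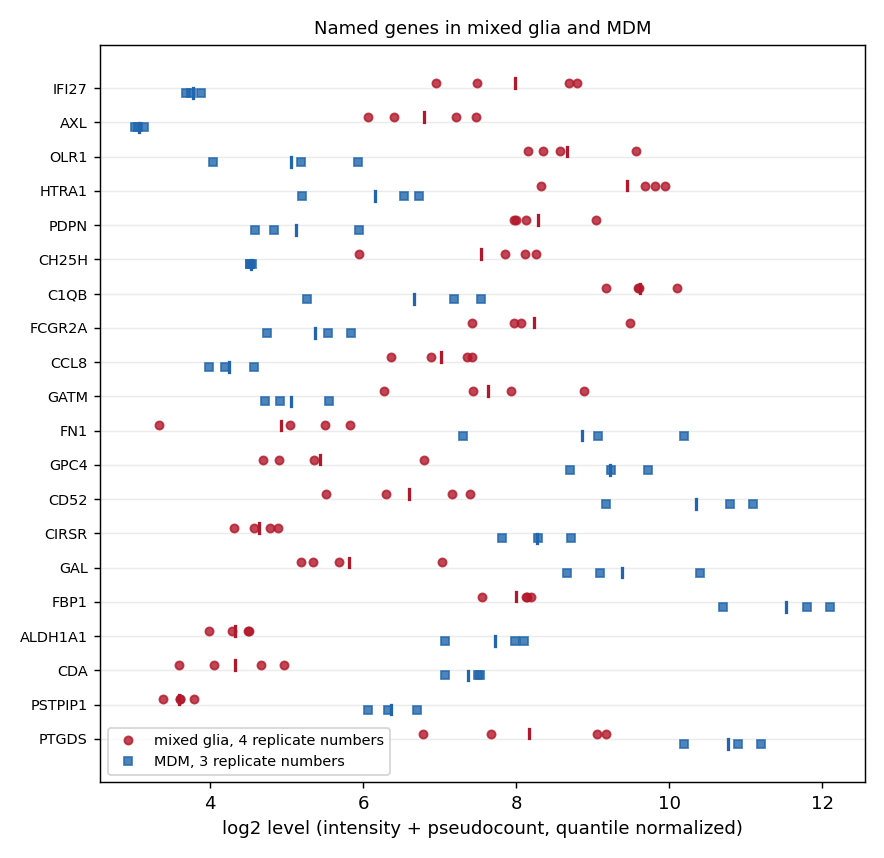
Each point is the mean log2 level of the arrays without and with serum of 1 replicate number (x axis, log2 of intensity plus pseudocount after quantile normalization) for the 20 genes named in the comparison of cell types (y axis), with red circles for the 4 mixed glia numbers, blue squares for the 3 MDM numbers and vertical bars for their means. For IFI27 the means are 7.98 in mixed glia and 3.77 in MDM, and for FBP1 they are 8.00 and 11.5.

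Genes typical of microglia were higher in mixed glia than in MDM. All 7 microglia-enriched genes were positive with a median of 0.98 (camera adjusted p = 2.7e-05, and 0.32 with an estimated correlation). C1QB and ADORA3, an adenosine receptor (2.30 ± 0.28, adjusted p = 0.0042), passed, and 4 members passed when adjusted over the list alone. Phagocytic and scavenger receptors had a median of 0.97 with 12 of 15 positive (camera adjusted p = 6.2e-05, and 0.32 with an estimated correlation). AXL, FCGR2A, FCGR3A (2.52 ± 0.47, adjusted p = 0.026) and TLR2 (1.74 ± 0.35, adjusted p = 0.035) passed, and adjusted over the list alone 8 were higher and 1 lower. All 8 complement genes were positive with a median of 0.94 (camera adjusted p = 0.00033, and 0.31 with an estimated correlation). C2 (1.71 ± 0.29, adjusted p = 0.018) and the inhibitor SERPING1 (1.40 ± 0.28, adjusted p = 0.036) passed beside C1QB, and 4 passed when adjusted over the list alone. The complement list shares C1QB with the microglia-enriched list and C3AR1 with the receptor list. The receptor list also shares MERTK with the microglia-enriched list and FCGR2A with the pan-myeloid list. It shares CD14, MSR1, MRC1 and CD163 with the monocyte and macrophage list. Interferon response genes had a median of 0.57 with 18 of 22 positive (camera adjusted p = 0.00021, and 0.47 with an estimated correlation). Of these IFI27 passed, and 3 passed when adjusted over the list alone. The interferon median was 0.36 without mixed glia replicate 16. In a test of the lists within each serum state, chosen after seeing the data, it was 0.87 without serum (19 of 22 positive, camera adjusted p = 4.5e-07, and 0.42 with an estimated correlation) and 0.16 with serum (14 of 22 positive, adjusted p = 0.36). MX1 had a log2 level of 7.96 in mixed glia against 5.15 in MDM without serum and 6.47 against 6.26 with serum. The receptor median was 0.61 without serum and 1.05 with serum, both past the threshold (adjusted p = 0.0022 and 7.1e-07). On the deposited scale ADORA3, FCGR3A, TLR2, C2 and SERPING1 lost their calls (adjusted p = 0.12, 0.064, 0.69, 0.77 and 1), and the receptor and complement medians were 0.49 and 0.25, the latter 0.31 with no filter.

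Genes of cholesterol and fatty acid synthesis were lower in mixed glia, with a median of -0.65 and 17 of 19 negative (camera adjusted p = 0.00016, and 0.47 with an estimated correlation). ACAT2, which makes acetoacetyl-CoA, passed at -1.80 ± 0.39 (adjusted p = 0.045) and was also the only member to pass when adjusted over the list alone, and its call was lost on the deposited scale (adjusted p = 0.18). INSIG1, a regulator of sterol synthesis, differed by -1.49 ± 0.46 and the desaturase FADS2 by -1.22 ± 0.63. That list's call was lost without the pairs of numbers 1 and 8 (median -0.32, adjusted p = 0.056), and within each serum state its median was -0.35 without serum and -0.87 with serum (adjusted p = 0.029 and 8.3e-06). The monocyte and macrophage list did not pass (median -0.15, camera adjusted p = 0.25), though CD52, the scavenger receptor MARCO (-2.45 ± 0.50, adjusted p = 0.037) and the lysozyme gene LYZ (-2.33 ± 0.33, adjusted p = 0.0082) were lower in mixed glia. Adjusted over the list alone, 2 of its members were higher and 4 lower. The pan-myeloid list had a median of 0.01 (camera adjusted p = 0.74), with FCGR2A as the 1 member to pass, over all probe sets and when adjusted over the list alone.

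Markers of other brain cells were measured beside these groups. Oligodendrocyte lineage genes were higher in mixed glia as a list, with a median of 0.87 and 11 of 12 positive (camera adjusted p = 0.02, and 0.65 with an estimated correlation), but none passed, over all probe sets or when adjusted over the list alone. CRYAB differed by 2.83 ± 1.07, GPM6B by 2.54 ± 1.18, the myelin gene MBP by 2.14 ± 1.15 and TF, transferrin, by 1.86 ± 0.93. Their SD between mixed glia numbers lay between 2.16 and 2.76. The list's call was lost without mixed glia replicate 18 (median 0.41, adjusted p = 0.20), without MDM replicate 14 (adjusted p = 0.11) and among the arrays with serum (median 0.72, adjusted p = 0.10). Astrocyte genes had a median of 0.22 (camera adjusted p = 0.15) with GFAP at a log2 level of 5.05 ± 1.8 in mixed glia against 4.08 ± 0.37 in MDM, where the median of the whole table was 5.21. Adjusted over the list alone 1 astrocyte gene passed. The fibroblast and mural list had a median of -0.43 (camera adjusted p = 0.25), with COL4A1 higher by 1.91 ± 0.33 (adjusted p = 0.018) and SPARC lower at -1.94 ± 0.38 (adjusted p = 0.034), and 1 higher and 2 lower when adjusted over the list alone. The neuronal list had a median of 0.07 (camera adjusted p = 0.58), with NEFH higher by 1.37 ± 0.25 (adjusted p = 0.024) and UCHL1 lower at -2.13 ± 0.38 (adjusted p = 0.021), and the same numbers when adjusted over the list alone.

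Within each serum state, the fifth and sixth comparisons gave counts. Without serum 131 probe sets differed between mixed glia and MDM in limma, 75 higher and 56 lower in mixed glia, and with serum 188 did, 94 higher and 94 lower. They had 82 probe sets in common, all 82 with the same direction. These comparisons are not independent, since both use the same 7 replicate numbers, whose arrays deviated together. Without serum the count was 76 when the array of replicate 7 was left out, 51 without MDM replicate 17 and 72 without MDM replicate 8. With serum it was 75 without MDM replicate 17, 111 without MDM replicate 8 and 111 without mixed glia replicate 18. Without the pairs of numbers 1 and 8 the counts were 55 without serum and 72 with serum, and on the deposited scale they were 13 (4 higher) and 24 (12 higher).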

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

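The test of astrocytes as a source of transcripts, the leaving out of numbers for the lists, the replicate block within 1 cell type, the splits that part all pairs and the sign choices of the pair differences were tests chosen after seeing the data.

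RNA quality measures stood apart for replicate 7 of mixed glia. Its array without serum had an ACTB 3 prime to 5 prime ratio of 13.7, where the other 3 of its group lay between 1.25 and 1.45, and a GAPDH ratio of 3.35 against 1.12 to 1.5. Its array with serum had an ACTB ratio of 2.56 against 1.03 to 1.14. Among the named genes, the mean log2 level of HTRA1 was 8.33 in mixed glia number 1 against 9.69 to 9.95 in the other 3, that of PDPN was 9.04 in number 7 against 7.97 to 8.13, and that of FBP1 was 7.56 in number 7 against 8.13 to 8.19. Among the lists, the median serum difference of pan-myeloid genes was 0.60 in the pair of replicate 16 against 0.18 to 0.24, and that of complement genes was 0.31 in the pair of replicate 7 against -0.34 to -0.30. In all, 8 of the 65 groups of 4 values had such a value far from the others, where chance gives about 1 in 20, or 3.2.

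Serum effects differed between mixed glia and MDM for 5 lists in camera, tested as the difference itself. The median difference was -0.76 for interferon response, 0.41 for inflammatory cytokines and NF-kB targets, 0.33 for phagocytic and scavenger receptors, 0.23 for hypoxia and glycolysis and -0.44 for cholesterol and fatty acid synthesis. None of the 5 held with an estimated correlation, where the lowest adjusted p was 0.31.

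Interferon response genes fell as a list with serum in mixed glia. If 1 replicate number carried it, the list median would be negative in few pairs or the call would end without that number. It was negative in 4 of 4 pairs. The list passed whichever number was left out, with camera adjusted p between 5.1e-09 and 0.0023 at the preset correlation. The fall was uneven, with pair medians of -0.133, -0.727, -1.10 and -0.281 for replicates 1, 7, 16 and 18. Without replicate 16 the list median was -0.455. If the array with the high 3 prime to 5 prime ratio made it, the median would shrink without replicate 7, but it was -0.622 there and -0.624 over all pairs (-0.27 on the deposited scale, where the median of all probe sets was 0.332). These values argue against 1 number or that array as the only source of the fall. Since 1 number was left out at a time, they cannot tell whether replicates 7 and 16 together carried most of it. A response of the cells to serum, which the design names, stays open as a hypothesis, as do other differences between the cultures, because no single gene passed without the block and the list did not pass with an estimated correlation (adjusted p = 0.29).

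More probe sets passed for serum in mixed glia than in MDM, 71 against 4 in fits of each cell type alone with the replicate block. A larger spread between MDM pairs is argued against, since the median SD of their differences was 0.774 times that of mixed glia pairs. The SD of the serum effects beyond the spread between pairs was 0.335 in mixed glia and 0.224 in MDM on the log2 scale, a gap that was not tested. The number of pairs may account for the gap: with 3 of the 4 mixed glia pairs the counts were 5, 162, 8 and 3 when replicate 1, 7, 16 or 18 was left out, and the lowest, 3, is below the 4 of MDM. For the difference between the serum effects itself no probe set passed in limma, without or with the replicate block (140 and 580, or 1.9% and 7.87%, at an unadjusted p under 0.05, where chance gives 5%), while 1 passed with array weights and 9 (8 higher, 1 lower) with the block once the number 7 pair was left out. The fit without the block keeps the spread between numbers in its error, so its 1.9% is no evidence against a difference.

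The genes higher in mixed glia than in MDM could come from other brain cells in the culture. Oligodendrocyte RNA would make them follow that list from array to array, and the median slope of the 82 called probe sets with a gene symbol was 0.00879, but the comparison selects against genes that vary between numbers (0 of 12 list members passed), so this slope, set out beforehand as evidence against such RNA, decides nothing. Astrocytes would raise their own markers, and the astrocyte list had a median difference of 0.215 with an upper quartile of 0.78. Both lie below the median of 1.87 of the called probe sets, the outcome set out as evidence against astrocytes. But those probe sets were selected for large and steady differences and the list was not, so this comparison decides nothing either. Of the most abundant members, GLUL and CLU (log2 levels of 10.86 and 8.26 against 9.94 and 9.20 in MDM) and MAG and CNP (8.10 and 8.08 against 7.54 and 7.90) had a high level in MDM that would hide a small share, while CRYAB, GPM6B, MBP and TF of the oligodendrocyte list differed by 2.83, 2.54, 2.14 and 1.86 without passing. S100B and GFAP of the astrocyte list, dim in MDM at 3.92 and 4.08, differed by 1.32 ± 0.45 and 0.97 ± 0.79 without passing. Of the 10 measured astrocyte genes 8 were higher and 2 lower in mixed glia. Oligodendrocyte cells or their RNA, astrocytes, other cell types and the difference of microglia from macrophages that the design names stay open.

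Other splits of the same arrays were counted for each comparison. For serum in mixed glia the real split gave 27 probe sets, and 2 of 35 splits of the 8 arrays gave as many, so chance is not excluded at 5%. The highest of the others gave 94 and set numbers 1 and 16 against 7 and 18 with all pairs kept together, which points to a structure of the samples by number. Because the numbers pair the samples, the real split is to be set against the 8 splits that part all 4 pairs: there it was the largest, and the highest of the others gave 1. These 8 are too few for a share under 5%. In the fit on pair differences alone the real signs gave 71 and the highest of the other 7 sign choices 0. For serum in MDM, 10 of 10 splits gave as many as the real count of 0, the highest of the others gave 1, and 10 splits are too few for a share under 5%. For the difference of serum effects, with 35 splits of the pair differences, the real count was 0 and the highest other 4. All 35 splits must give at least 0, so they say nothing about chance, and the same holds for MDM. For the cell types averaged over serum, 1 of 35 splits gave as many as the real 155 and the highest other gave 2. Without serum it was 1 of 35 with the real count at 131 and the highest other at 9, and with serum 1 of 35 with 188 and 16. For each of these 3 the share is under 5%, and 1 of 35 is the smallest that 35 splits can give. The 3 use the same 7 replicate numbers and are not independent of each other.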

How the results depend on the processing

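Leaving out arrays by brightness or RNA quality, the replicate block within 1 cell type or with pairs left out, leaving out numbers for the lists and testing lists within 1 serum state were tests chosen after seeing the data. Among the counts of probe sets, limma-trend, centring, both other pseudocounts, the stricter filter, 1 probe set per gene and the 2-fold minimum stayed within 1.5 times the values reported, and for each change below the cause was not tested unless stated. No filter gave 16 for serum in mixed glia and 95 for the cell types averaged over serum, with more probe sets in the adjustment. The deposited scale gave 13 (13 higher, 0 lower) for serum in mixed glia, 49 for the cell types, 13 without serum and 24 with serum. On that scale the median of all probe sets was 0.332 for serum in mixed glia, 0.234 for serum in MDM, -0.187 for the cell types, -0.235 without serum and -0.131 with serum, against -0.0157 to -0.0102 after normalization. Array weights, whose estimation did not fully converge, gave 68 for serum in mixed glia, 50 in MDM, 1 for the difference, 556 for the cell types, 226 without serum and 1213 with serum.

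The replicate block gave 201 for serum in mixed glia (101 higher and 100 lower against 23 and 4) and 1 in MDM, and changed no other count by more than 1.5 times. For the cell types the fit of 14 arrays with no replicate block gave 514. Fitted on that cell type alone, serum in mixed glia gave 16, and with the replicate block 71 and in MDM 4. With the replicate block but without the number 7 pair the counts were 275, 11 for MDM and 9 for the difference, and without the pairs of numbers 1 and 8 the block gave 48 for mixed glia. Without those pairs and the block they were 0 for serum in mixed glia, 56 for the cell types, 55 without serum and 72 with serum, with fewer samples. Leaving out the array of number 7 without serum gave 76 for the cell types without serum.

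Leaving out each replicate number gave 5 to 39 for serum in mixed glia, 0 to 0 for serum in MDM and for the difference, 56 to 120 for the cell types, 51 to 105 without serum and 75 to 146 with serum. The lists past the threshold then numbered 9 to 10 for serum in mixed glia, 5 to 7 in MDM, 3 to 7 for the difference and 5 to 8 for the cell types. Of the lists reported, 8 to 10 of 10, 4 to 6 of 6, 3 to 5 of 5 and 5 to 6 of 6 were among them. An estimated correlation left 4, 0, 0 and 0 of these lists, and fry, which does not compare a list with other genes, 4, 0, 0 and 3. Within 1 serum state the lists for the cell types numbered 6 without serum and 5 with serum. The deposited scale gave 10 lists for MDM, and no filter 8 for the difference. With the replicate block the list of monocytes and macrophages was lost in mixed glia and that of the lysosome gained for the difference, and of the named genes 18 values in mixed glia and 1 in MDM gained a call, with no other call changed. The lysosome list in mixed glia was lost with the mean over all probe sets of a gene and the matrix list in MDM with no filter. On the deposited scale the interferon list in mixed glia had a median of -0.27. Of the named genes, C1QB reversed for serum in mixed glia, where it had not passed, with values from -0.0511 (without replicate 7) to 1.01 (without replicate 1). The other named genes kept their direction on the deposited scale, with the block and with each number left out. Without the block, leaving out a number ended the call of 38 of 192 mixed glia values and 39 of 280 for cell types. Dim arrays have less signal over background, and no background was measured here.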

Other observations

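The MHC class II values per pair and the look at single genes of lists that did not pass were tests chosen after the results were seen. Lists that did not pass for serum in mixed glia still held single genes past the threshold, without or with the replicate block. In the immediate early serum response list (median 0.20, camera adjusted p = 0.11) ZFP36 rose by 1.71 ± 0.25 (adjusted p = 0.005), while IER3 differed by 2.05 ± 0.59 and the stress factor ATF3 by -1.72 ± 0.50, and these passed with the replicate block (adjusted p = 0.011 and 0.031). Adjusted over the list alone, 2 were higher and 1 lower. In the list of amino acid and unfolded protein stress (median -0.01, camera adjusted p = 0.41) the factor DDIT3 differed by -1.48 ± 0.40 and the asparagine synthetase ASNS by -1.33 ± 0.44, both past the threshold with the block (adjusted p = 0.0065 and 0.015), and 1 was lower when adjusted over the list alone. In the list of oxidative stress and metal response (median -0.18, camera adjusted p = 0.81) the metallothionein MT1X differed by 1.60 ± 0.52, HMOX1 by 1.09 ± 0.40 and GCLC, of glutathione synthesis, by -1.09 ± 0.27. HMOX1 and GCLC passed with the block (adjusted p = 0.022 and 0.017), and 1 was lower when adjusted over the list alone.

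The remaining lists did not pass in mixed glia. Their medians and camera adjusted p were 0.25 and 0.15 for MHC class II presentation, -0.07 and 0.80 for cell cycle, -0.03 and 0.73 for cholesterol and fatty acid synthesis, 0.20 and 0.15 for heat shock and -0.26 and 0.54 for complement. For other cell types they were 0.26 and 0.54 for astrocyte genes, 0.22 and 0.34 for neuronal genes, 0.21 and 0.54 for fibroblast and mural genes, 0.06 and 0.73 for endothelial genes and -0.02 and 0.76 for lymphocyte genes. SLC1A3 of the astrocyte list differed by -0.99 ± 0.23 with serum and passed with the block (adjusted p = 0.014) and when adjusted over the list alone. In the MHC class II list the median serum difference was 1.62 in the pair of replicate 7 and between -0.35 and 0.11 in the other 3 pairs.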
